A study of Homo sapiens with 15 samples.

How the data were processed

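The series holds RNA-seq of A375 melanoma cells in 15 libraries: 3 each of cells in 10% FBS, cells starved in 0.1% FBS for 48 hours, and cells with a control vector, MKL1 or caMKL1 overexpressed for 48 hours. Per the labels' protocols, total RNA was extracted with Trizol, messenger RNA was enriched with oligo(dT) beads, and libraries were made with a NEBNext Ultra RNA kit. Per the submitters' processing notes, Bowtie2 2.2.8, HISAT2 2.2.4, StringTie 1.3.1, RSEM, DESeq2 and the GRCh38 genome were used, with no role or order stated. The annotation release, and whether counting used the strand of the reads, are not given in the sources used here. Each of 3 deposited tables holds a pair of groups: 10% with 0.1% FBS (20332 genes), control vector with MKL1 (20323 genes) and control vector with caMKL1 (20323 genes).

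The counts per gene and library were used as deposited; per the file headers they are counts, and they are whole numbers that sum to a different total in each library, but RSEM is named in the notes, so they can be estimated counts that the authors rounded. Without strand, reads of genes that overlap on opposite strands cannot be told apart, and RSEM or another counter can split reads between near copies. The authors also deposited FPKM values per library and the mean FPKM per group, in which 0 was replaced by 0.001; the mean columns differed from means of the FPKM values by at most 0.000667, and neither was used for testing. The deposited log2 values are the authors' log2 fold changes, per the file headers. The deposited p-values and adjusted p-values come from the authors' own test, which the file headers do not name; they were compared with the tests made here. The control vector counts were identical in the overexpression tables for all 20323 genes. No count in any library was recorded for 3039, 3042 and 2857 genes of the 3 tables.

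Counts were tested with edgeR 4.0.16 in R 4.3.3: TMM normalization, filterByExpr on the groups of the fit, and the quasi-likelihood test (glmQLFit, glmQLFTest, two-sided) with Benjamini-Hochberg adjustment and a threshold of 0.05. The starvation, MKL1 and caMKL1 comparisons were each fitted on their own 6 libraries, and caMKL1 was compared with MKL1 in a fit of the 9 overexpression libraries. SEs of single genes are the absolute log2 fold change divided by the square root of F. CPM are counts scaled to a common library size with the TMM factors, given as mean ± SD over 3 libraries, within the fit of the comparison. A fold against a group with no counts is a lower bound against a floor of 3 counts over that group, which covers counting error only. The comparisons, tests, alternatives, gene lists and the rule for named genes were chosen before the data were examined, except where stated otherwise.

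The rule names, for each comparison, MRTFA and SRF; the 8 genes with the largest rise and the 8 with the largest fall among genes with a symbol, an adjusted p under 0.05, a mean of at least 1 CPM and groups that do not overlap in CPM; up to 4 measured members of each gene list by smallest p; and ICAM1, CD274, B2M, ACTB, ACTA2, CCN1, CCN2, FOS and EGR1 whatever their values. Some genes that the rule names are not reported here. A gene named in one comparison may be given its value in another. The 21 lists cover MRTF-SRF cytoskeletal targets, immediate early genes, YAP-TAZ targets, mitosis and DNA replication, MHC class I antigen presentation, interferon-stimulated genes, checkpoint ligands, lymphocyte adhesion with ligands and death receptors, cholesterol biosynthesis, FOXO and quiescence genes, melanocyte differentiation, dedifferentiated melanoma, extracellular matrix, MAPK pathway output, the ATF4 stress response, glycolysis, ribosome biogenesis, lysosome and autophagy, and markers of lymphocytes, fibroblasts and epithelia. Lists were tested with camera of limma 3.58.1 (two-sided, preset inter-gene correlation of 0.01, Benjamini-Hochberg adjustment over the lists of a comparison); camera with an estimated correlation and fry were run beside it. "Adjusted over the list alone" counts members after adjustment within their list. Coordinates, overlaps and exonic lengths come from a GENCODE annotation of GRCh38.

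The tests were checked on simulated counts with 200 genes changed, drawn from the means and library sizes of each comparison. In the starvation comparison (13200 genes) 89.55%, 96.92% and 98.46% of genes changed by 1.5-fold, 2-fold and 4-fold were recovered, and 7.522% of calls were false. For MKL1 (13313 genes) these were 77.61%, 93.94% and 100%, with 6.481% false; for caMKL1 (13429 genes) 87.88%, 96.97% and 100%, with 7.143% false; and for caMKL1 against MKL1 (13567 genes) 80.6%, 95.52% and 100%, with 5.505% false. The false shares lie somewhat above the 5% aimed at. In the real comparisons between 31.19% and 63.6% of the tested genes passed, a far larger share than was changed in the simulations. The recovered and false shares therefore need not hold for the real calls. In the same simulations 1 gene list was shifted 1.5-fold; camera passed 1, 1, 2 and 4 lists in these 4 comparisons, the shifted list among them each time, so it also passed lists that had not been shifted as a whole.

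The total counts ran from 13937251 to 23957043 per library. Pairs of replicates differed by a chi-square per degree of freedom of 1.808 to 8.367, where counting error alone gives about 1. The pairs that differed most were control vector replicates 1 and 3 (8.367), 10% FBS replicates 2 and 3 (7.29) and control vector replicates 1 and 2 (6.182). The 50 most abundant genes took between 13.2% and 15.8% of the counts of a library, mitochondrial genes between 3.20% and 6.42% and ribosomal protein genes between 3.77% and 4.98%. The labels give no batch or date.

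The alternatives tried were DESeq2 1.42.0 (Wald test), its size factors in edgeR, no filter and a stricter filter on low counts (at least 1 CPM in 3 libraries and a mean count of 50), a 2-fold threshold, a replicate block, a joint fit of the 9 overexpression libraries, and each library left out in turn. Scaling by library totals and 4 further textbook gene lists were added after seeing the data. Tables were read with pandas 2.3.3 in Python 3.11.15 and plots drawn with matplotlib 3.10.9.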

Results

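Polyadenylated RNA of A375 cells, an established human melanoma line, was sequenced in 15 libraries that fall into 5 groups of 3. In the starvation set, cells kept in 10% fetal bovine serum (FBS) were set against cells kept for 48 hours in 0.1% FBS. In the overexpression set, cells carried a control vector, overexpressed MKL1, or overexpressed caMKL1, a constitutively active form, for 48 hours. MKL1, approved symbol MRTFA, is a coactivator of serum response factor (SRF) that binds monomeric actin and moves into the nucleus when actin polymerizes. The series as a whole concerns melanoma cells and killing by cytotoxic T lymphocytes, but no lymphocytes are named in the labels of these libraries. The total counts were 17178725, 16890187 and 15801033 in 10% FBS and 16673427, 16464181 and 13937251 in 0.1% FBS. They were 22463063, 20784978 and 23957043 with the control vector, 22945914, 20387727 and 23501312 with MKL1, and 20895879, 17850868 and 16557803 with caMKL1. At these depths 3 counts in a library corresponded to between 0.125 and 0.215 CPM (counts scaled for library size), and the floor used for genes with no counts, 3 counts over a whole group, to between 0.0437 and 0.063 CPM. The labels do not say whether the 3 replicates of a group were separate cultures, so they may be technical. On principal components, the first axis held 81% of the variance of the starvation set and parted the serum levels, and 77.5% of the variance of the overexpression set, where it set caMKL1 apart from the other groups.

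The overexpressed gene was examined in every library first. MRTFA (ENSG00000196588, GRCh38 chromosome 22, 40410281 to 40636702) was at 26.2, 25.7 and 25.8 CPM in the control vector libraries, at 732, 771 and 709 CPM with MKL1, and at 481, 463 and 465 CPM with caMKL1. MRTFA counts were therefore raised in the libraries labelled with either form. Gene counts do not tell caMKL1 from MKL1, nor the introduced transcript from the cell's own. MRTFA counts were lower with caMKL1 than with MKL1 (log2 fold change -0.65 ± 0.0384 SE, adjusted p = 1.91e-10, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). The lengths of the constructs are not given in the sources used here, so lower counts need not mean fewer transcripts. In the starvation set MRTFA was at 19.7, 22.4 and 18.2 CPM in 10% FBS and at 15.9, 16.6 and 16.0 CPM in 0.1% FBS. SRF (ENSG00000112658, chromosome 6, 43171299 to 43181507), the DNA-binding partner of MKL1, was at 69.5, 64.0 and 62.0 CPM with the control vector, at 69.5, 74.3 and 70.1 CPM with MKL1, and at 272, 264 and 263 CPM with caMKL1. It was at 44.0, 41.9 and 38.9 CPM in 10% FBS and at 49.2, 43.8 and 43.2 CPM in 0.1% FBS.

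**Figure D1:**
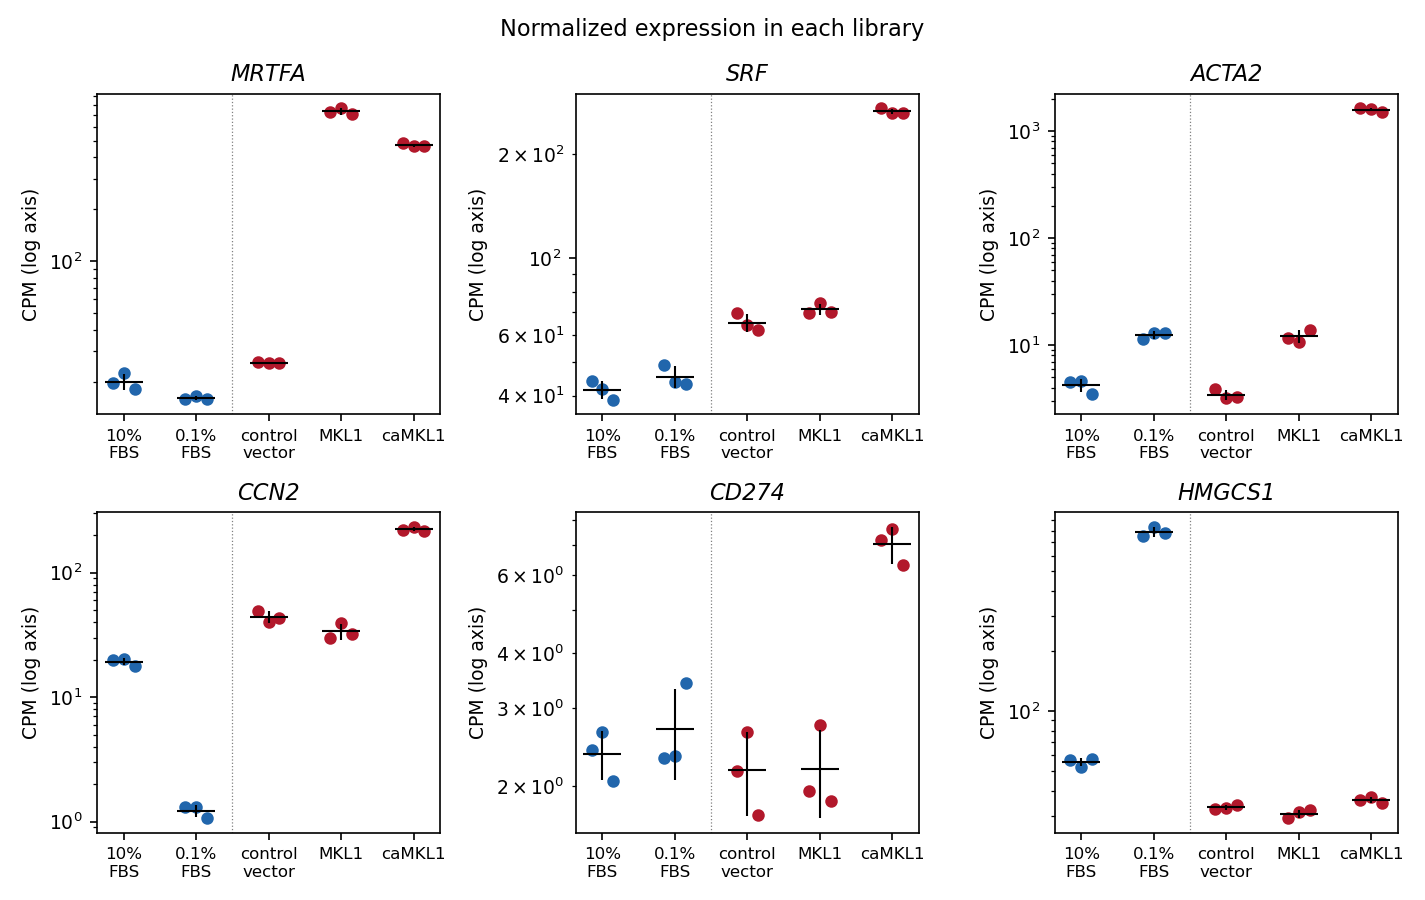
CPM (log axis) of MRTFA, SRF, ACTA2, CCN2, CD274 and HMGCS1 in each of the 15 libraries, with the group mean as a dash and its SD as a bar; blue points are the starvation set and red points the overexpression set, and the 2 sets were normalized separately, so levels are compared within a set. MRTFA lies between 463 and 771 CPM in the MKL1 and caMKL1 libraries and between 25.7 and 26.2 CPM in the control vector libraries.

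The starvation comparison asks what changed in A375 cells when most of the serum was withdrawn. In 0.1% FBS, enzymes of cholesterol synthesis and genes of cell cycle exit were higher, and genes of mitosis and DNA replication were lower. HMGCS1 (ENSG00000112972, chromosome 5, 43289395 to 43313512), which feeds the mevalonate pathway, was at 787 ± 46.0 CPM in 0.1% FBS against 55.7 ± 2.61 CPM in 10% FBS (SD, n = 3 each). The protease inhibitor gene A2M (ENSG00000175899, chromosome 12, 9067664 to 9116229) was at 438 ± 28.2 against 17.4 ± 0.388 CPM, a log2 fold change of 4.65 ± 0.0632 SE (adjusted p = 1.1e-15, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). The matricellular gene CCN2 (ENSG00000118523, chromosome 6, 131948176 to 131951373) went the other way, at 1.23 ± 0.141 against 19.3 ± 1.35 CPM, a log2 fold change of -3.96 ± 0.144 SE. In all, 8333 of 13307 tested genes passed an adjusted p of 0.05, 4150 higher and 4183 lower in 0.1% FBS, and 998 of them differed at least 2-fold (632 higher, 366 lower).

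The largest rises in 0.1% FBS, as log2 fold changes, were those of RASD1 (5.15), A2M, CA9 (4.39), HGF (4.30), PLA2G3 (4.23), OLFM3 (4.17), PRUNE2 (3.96) and SCHIP1 (3.96). CA9 encodes carbonic anhydrase 9 and HGF encodes hepatocyte growth factor. The largest falls were those of the hair keratin KRT81 (-5.75), EFEMP1 (-4.73), the keratin KRT80 (-4.37), ATOH8 (-4.08), CCN2, THBS1 (-3.79), CPA4 (-3.42) and PTX3 (-3.16). THBS1, which encodes the matrix protein thrombospondin 1, was at 20.2 ± 1.76 CPM in 0.1% FBS against 280.0 ± 20.6 CPM in 10% FBS. Reads of KRT81 can be shared with its near copy KRT86, those of SCHIP1 with the fusion gene IQCJ-SCHIP1, and CA9 and THBS1 overlap ARHGEF39 and FSIP1 on the opposite strand, so these counts are uncertain.

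Of the 22 measured genes of cholesterol biosynthesis, 21 rose and none fell (list median log2 fold change 1.83; camera, adjusted p = 1.45e-90, and adjusted p = 0.00649 with an estimated correlation). Besides HMGCS1 (3.82), INSIG1 (3.31), MSMO1 (2.64) and IDI1 (2.24) rose. Of 37 genes of mitosis and DNA replication, 36 fell and 0 rose (median -0.78; camera, adjusted p = 7.24e-32, and adjusted p = 0.0264 with an estimated correlation). CDC20 (-1.61), PLK1 (-1.53) and KIF20A (-1.43), which act in mitosis, fell, as did the proliferation marker MKI67 (-1.04). Of 17 FOXO and quiescence genes, 15 rose and 1 fell (median 0.77; camera, adjusted p = 3.81e-10, and adjusted p = 0.0293 with an estimated correlation). CDKN1A (2.27), which encodes the cell cycle inhibitor p21, rose with CCNG2 (1.59), PDK4 (1.36) and YPEL5 (1.21).

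Genes that respond to actin and to cell adhesion went mostly down. Of 34 measured MRTF-SRF cytoskeletal targets, 22 fell and 8 rose (median -0.37; camera, adjusted p = 0.000281). That call was lost at adjusted p = 0.106 with an estimated correlation. FLNA (-1.17), TPM1 (-1.28), CNN3 (-1.22) and ACTB (-0.88) fell, while ACTA2 (ENSG00000107796, chromosome 10, 88935074 to 88991339), the smooth muscle actin gene, rose from 4.22 ± 0.61 to 12.5 ± 0.983 CPM (log2 fold change 1.56 ± 0.134 SE). ACTA2 shares 380 exonic bases with FAS on the opposite strand, and FAS rose by nearly the same factor (1.59 ± 0.0738 SE), so the rise of ACTA2 is uncertain. SRF was at 45.4 ± 3.28 against 41.6 ± 2.53 CPM and did not pass the test (0.13, adjusted p = 0.122, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), and MRTFA fell (-0.32, adjusted p = 0.00725, by the same test and adjustment of edgeR). Of 22 YAP-TAZ targets, 14 fell and 6 rose (median -0.53; camera, adjusted p = 0.000467, lost at adjusted p = 0.106 with an estimated correlation). AXL (-2.69), CCN2 and CCN1 (-2.46) fell and IGFBP3 (2.19) rose. Of 27 extracellular matrix genes, 18 fell and 6 rose (median -0.36; camera, adjusted p = 1.43e-07, lost at adjusted p = 0.0618 with an estimated correlation), with falls of TNC (-1.54), COL5A2 (-1.69) and TIMP3 (-1.11).

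Immediate early genes were higher in the starved cells: 15 of 22 rose and 2 fell (median 0.53; camera, adjusted p = 1.3e-05, lost at adjusted p = 0.0959 with an estimated correlation). The nuclear receptor genes NR4A2 (3.20), NR4A3 (3.14) and NR4A1 (1.88) rose, with EGR1 (1.27) and FOS (0.97). Of 22 lysosome and autophagy genes, 12 rose and 2 fell (median 0.26; camera, adjusted p = 0.000854, lost at adjusted p = 0.23 with an estimated correlation), among them MAP1LC3B (0.96) and SQSTM1 (1.00), the latter overlapping MRNIP. Of 25 ribosome biogenesis genes, 20 fell and 2 rose (median -0.35; camera, adjusted p = 0.000152, lost at adjusted p = 0.0618 with an estimated correlation), among them FBL (-0.61) and NPM1 (-0.45). Of 21 genes of the dedifferentiated melanoma state, 10 fell and 4 rose (median -0.28; camera, adjusted p = 0.000359, lost at adjusted p = 0.0618 with an estimated correlation), with CAV1 (-1.92) and FOSL1 (-1.16) among those that fell. Of 9 melanocyte differentiation genes, 5 rose and 2 fell (median 0.25; camera, adjusted p = 0.025, lost at adjusted p = 0.125 with an estimated correlation). GPNMB (1.51) and MITF (0.77), the melanocyte lineage regulator, rose and SOX10 (-0.38) fell. The melanocyte call also rested on replicate 3 of 10% FBS, without which its adjusted p was 0.0593 (range over the camera alternatives 0.0255 to 0.125).

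Genes that bear on recognition and killing by lymphocytes moved in several directions. Of 21 genes of lymphocyte adhesion, activating ligands and death receptors, 12 rose and 3 fell (median 0.23; camera, adjusted p = 0.00547, lost at adjusted p = 0.128 with an estimated correlation). The death receptor genes FAS (ENSG00000026103, chromosome 10, 88990582 to 89015785; from 12.6 ± 0.665 to 38.1 ± 1.19 CPM) and TNFRSF10B (0.72) rose, as did the caspase inhibitor gene XIAP (1.02) and the NKG2D ligand gene MICA (1.11). ICAM1 (0.33) and B2M (0.23) rose. CD274 (ENSG00000120217, chromosome 9, 5450503 to 5470566), which encodes PD-L1, was at 2.69 ± 0.631 against 2.37 ± 0.299 CPM and did not pass the test (adjusted p = 0.528, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Neither the 20 genes of MHC class I antigen presentation (6 rose, 7 fell; camera, adjusted p = 0.672) nor the 28 interferon-stimulated genes (4 rose, 12 fell; adjusted p = 0.306) nor the 11 checkpoint ligands (2 rose, 2 fell; adjusted p = 0.982) passed the list test. Among them HLA-B (0.87) and NT5E (0.75) rose, and PSME2 (-0.68), IFIT1 (-1.19) and NECTIN2 (-0.75) fell. Near-identical HLA genes can share reads.

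Of 21 glycolysis genes, 9 rose and 10 fell, and the list median (-0.10) was below 0 while its mean (0.21) and the test were upward (camera, adjusted p = 0.0495, lost at adjusted p = 0.571 with an estimated correlation). ALDOC (1.35), PDK1 (1.28) and HK2 (1.04) rose. The glycolysis call was lost without replicate 3 of 10% FBS (adjusted p = 0.149) and without replicate 1 of 0.1% FBS (0.0796), within a range of 0.0187 to 0.571 over the camera alternatives. The MAPK pathway list (9 rose and 5 fell of 17; camera, adjusted p = 0.0637) and the ATF4 stress response list (9 rose and 11 fell of 24; adjusted p = 0.0618) did not pass, although DUSP5 (1.59) and PPP1R15A (0.95) rose and PHGDH (-1.32) and ASNS (-1.21) fell. The ATF4 list passed without replicate 1 (0.0466) or replicate 3 (0.0285) of 10% FBS, within a range of 0.0285 to 0.333 over the camera alternatives, and the MAPK list passed when scaled by library totals (0.0497; range over the camera alternatives 0.0497 to 0.163). Of 5 measured epithelial markers 3 fell and 0 rose (camera, adjusted p = 0.0014, lost at adjusted p = 0.108 with an estimated correlation), with KRT8 at -2.07; this gene overlaps KRT18 on the opposite strand. The lymphocyte markers (2 rose and 0 fell of 3; adjusted p = 0.556) and fibroblast markers (2 rose and 2 fell of 6; adjusted p = 0.982) did not pass. PTPRC, a leukocyte marker, was at 1.04 ± 0.173 against 0.425 ± 0.154 CPM, and the fibroblast markers FAP (2.63) and POSTN (-3.21) changed in opposite directions. The median and mean of the checkpoint list (0.13 and -0.0437) and of the fibroblast list (0.13 and -0.387) differed in sign. Adjusted over the list alone, the counts were the same as those given except that 11 interferon-stimulated genes fell, 10 MAPK pathway genes rose and 21 ribosome biogenesis genes fell. Of the 21 lists tested, 14 passed with the preset correlation and 3 with an estimated correlation.

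The MKL1 comparison asks which genes respond to more of the wild-type coactivator. With MKL1, 20 of 34 MRTF-SRF targets rose, 12 of 25 matrix genes fell, and 24 of 37 genes of mitosis and DNA replication fell. The calls of these 3 lists were lost at adjusted p = 0.1, adjusted p = 0.212 and adjusted p = 0.389 with an estimated correlation in camera. ACTA2 was at 12.3 ± 1.75 CPM against 3.47 ± 0.364 CPM with the control vector (SD, n = 3 each; log2 fold change 1.83 ± 0.132 SE). MYL9 (ENSG00000101335, chromosome 20, 36541484 to 36551447), which encodes a myosin light chain, was at 38.1 ± 3.1 against 5.57 ± 0.732 CPM (2.76 ± 0.0978 SE). The fibrillar collagen gene COL5A1 (ENSG00000130635, chromosome 9, 134641774 to 134844843) was at 19.5 ± 0.668 against 77.5 ± 1.4 CPM (-1.99 ± 0.0562 SE). In all, 4182 of 13409 tested genes passed, 2114 higher and 2068 lower with MKL1, and 177 differed at least 2-fold (135 higher, 42 lower). Scaled by library totals 2534 were higher and 1683 lower, and in a fit of all 9 overexpression libraries 2171 were higher and 2657 lower, so the balance of directions depends on the scaling and the fit. Without replicate 3 of MKL1 the count of changed genes dropped to 2595.

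After MRTFA itself (4.85), the largest rises were those of MYL9, NXF2B (2.26), LCP1 (2.05), KRT86 (2.05), IL24 (1.86), TCN1 (1.83) and ACTA2. The largest falls were those of MGP (-2.57), ALPP (-2.08), COL5A1, IGFBP5 (-1.42), ADRA1B (-1.42), COL5A3 (-1.35), TGFBI (-1.32) and SERPINF1 (-1.30). MGP, matrix Gla protein, and TGFBI are secreted matrix proteins. NXF2B, KRT86 and ALPP have near copies (NXF2, KRT81 and the other placental-type phosphatases) with which reads can be shared. The rise of NXF2B did not pass with DESeq2 (adjusted p = 0.297), which was the highest adjusted p over its alternatives (lowest 1.04e-05).

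Of 34 measured MRTF-SRF cytoskeletal targets, 20 rose and 0 fell (median 0.23; camera, adjusted p = 3.03e-17, lost at adjusted p = 0.1 with an estimated correlation). Besides MYL9 and ACTA2, GLIPR1 (1.55), which overlaps KRR1, and TPM2 (0.59) rose, and ACTB (0.21) rose slightly. SRF was at 72.5 ± 2.47 against 65.4 ± 3.88 CPM (0.15, adjusted p = 0.0536, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). It passed without replicate 1 of the control vector (log2 fold change 0.19, adjusted p = 0.0057), with library totals (adjusted p = 0.0231), with the stricter filter (0.0409) and in a fit of all 9 overexpression libraries (0.0492), within a range of 0.0057 to 0.232 over all alternatives in edgeR and DESeq2. Of the 22 YAP-TAZ targets 3 rose and 4 fell (camera, adjusted p = 0.0713), with a pass without replicate 2 of MKL1 (0.0335; range over the camera alternatives 0.0335 to 0.389). IGFBP3 (-1.06) fell, and CCN1 was at 37.5 ± 2.83 against 41.0 ± 1.98 CPM (-0.13, adjusted p = 0.159, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). CCN2 fell (-0.36, adjusted p = 0.0107, by the same test and adjustment of edgeR), but not without replicate 1 (0.0599) or replicate 3 (0.0529) of MKL1, within a range of 0.00197 to 0.0599.

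Of 25 extracellular matrix genes, 12 fell and 7 rose (median -0.11; camera, adjusted p = 2.81e-10, lost at adjusted p = 0.212 with an estimated correlation), with falls of FN1 (-1.09), the fibronectin gene, and COL6A3 (-1.05). Of 37 genes of mitosis and DNA replication, 24 fell and 2 rose (median -0.22; camera, adjusted p = 7.28e-11, lost at adjusted p = 0.389 with an estimated correlation), among them MCM5 (-0.59), RRM2 (-0.53) and MYBL2 (-0.55). Of 25 ribosome biogenesis genes, 13 fell and 0 rose (median -0.17; camera, adjusted p = 1.3e-05, lost at adjusted p = 0.402 with an estimated correlation), DKC1 (-0.31) among them. Of 24 genes of the ATF4 stress response, 12 fell and 1 rose (median -0.19; camera, adjusted p = 0.000791, lost at adjusted p = 0.456 with an estimated correlation), with STC2 (-0.63) and ATF4 itself (-0.30) among those that fell. Of 22 cholesterol biosynthesis genes, 10 fell and 0 rose (median -0.13; camera, adjusted p = 0.013, lost at adjusted p = 0.212 with an estimated correlation), EBP (-0.38) among them. Of 17 FOXO and quiescence genes, 8 rose and 1 fell (median 0.17; camera, adjusted p = 0.00524, lost at adjusted p = 0.419 with an estimated correlation), with rises of CDKN1A (0.61) and SESN1 (0.64) and a fall of CDKN1C (-0.66).

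Of 26 interferon-stimulated genes, 11 rose and 4 fell (median 0.25; camera, adjusted p = 0.00524, lost at adjusted p = 0.212 with an estimated correlation). The guanylate-binding protein gene GBP1 (1.79) rose most of those named by the smallest p, with IFI6 (0.68), OAS1 (0.43) and GBP2 (0.41). Of 10 checkpoint ligands 5 rose and 0 fell (camera, adjusted p = 0.138), CEACAM1 (1.60) among them, and CD274 was at 2.22 ± 0.492 against 2.19 ± 0.47 CPM (adjusted p = 0.957, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). ICAM1 (-0.13, adjusted p = 0.0915) and B2M (0.0152, adjusted p = 0.8) did not pass that test in edgeR; ICAM1 passed in a fit of all 9 overexpression libraries (0.0333; range over alternatives 0.0333 to 0.286). Genes of MHC class I antigen presentation (2 rose and 5 fell of 20; camera, adjusted p = 0.609) and of lymphocyte adhesion, ligands and death receptors (1 rose and 2 fell of 21; adjusted p = 0.796) did not pass as lists. Among them NLRC5 (0.42), a transactivator of MHC class I genes, and FAS (0.38) rose and FADD (-0.28) fell. FAS overlaps ACTA2, which also rose, on the opposite strand, so the rise of FAS is uncertain.

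The lists of immediate early genes (4 rose and 4 fell of 22; camera, adjusted p = 0.97), melanocyte differentiation (3 rose and 0 fell of 11; 0.609), dedifferentiated melanoma (2 rose and 4 fell of 19; 0.32), MAPK pathway output (5 rose and 5 fell of 17; 0.948) and lysosome and autophagy (8 rose and 4 fell of 22; 0.376) did not pass. Within them EGR1 (0.34), MITF (0.44) and BIRC3 (1.46) rose, while FOS was at 5.41 ± 0.144 against 5.87 ± 0.543 CPM (adjusted p = 0.499, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). Glycolysis genes (2 rose and 7 fell of 21; camera, adjusted p = 0.0713) passed without replicate 2 (0.0343) or replicate 3 (0.0281) of the control vector or replicate 1 of MKL1 (0.0432), within a range of 0.0281 to 0.715 over the camera alternatives. Markers of lymphocytes (0 rose and 0 fell of 3; camera, adjusted p = 0.992), fibroblasts (1 rose and 0 fell of 5; 0.34) and epithelia (1 rose and 3 fell of 5; 0.731) did not pass, though LUM (1.06) and KRT8 (0.55) rose. In the immediate early, melanocyte, dedifferentiated, MAPK and lymphocyte lists the signs of median, mean and test differed. Adjusted over the list alone, 23 MRTF-SRF targets rose, 12 interferon-stimulated genes rose, 1 checkpoint ligand fell, 1 gene of lymphocyte adhesion, ligands and death receptors fell, 9 FOXO genes rose and 2 fell, 8 matrix genes rose, 7 MAPK genes rose and 6 fell, 2 ATF4 genes rose, 8 glycolysis genes fell and 16 ribosome biogenesis genes fell, and all other counts were as given. Of the 21 lists 8 passed with the preset correlation. With a correlation estimated by limma's camera 0 passed (4 at an unadjusted p under 0.05), and limma's fry, which tests a list without comparing it with other genes, passed 11.

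The caMKL1 comparison asks what the constitutively active form changes. With caMKL1, 35 of 36 MRTF-SRF targets rose, many by large factors, and all 25 measured ribosome biogenesis genes fell. In addition 10 of 12 checkpoint ligands rose and 34 of 37 genes of mitosis and DNA replication fell, list calls that were lost at adjusted p = 0.0812 and adjusted p = 0.149 with an estimated correlation in camera. VTCN1 among these ligands and CNN1 among the MRTF-SRF targets were tested only because of their level with caMKL1. ACTA2 was at 1559 ± 53.9 CPM against 3.41 ± 0.359 CPM with the control vector (SD, n = 3 each; log2 fold change 8.83 ± 0.0669 SE, adjusted p = 5.69e-19, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). The cardiac actin gene ACTC1 (ENSG00000159251, chromosome 15, 34788095 to 34795726) was at 313 ± 7.2 CPM with caMKL1 and had no count with the control vector, which makes it at least 7070-fold higher given a floor of 3 counts over the control group. SRF was at 263 ± 5.0 against 64.2 ± 3.82 CPM (2.03 ± 0.0489 SE). Actin genes are alike in their coding sequence and can share reads. In all, 8623 of 13558 tested genes passed, 4136 higher and 4487 lower with caMKL1, and 1282 differed at least 2-fold (1087 higher, 195 lower).

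The largest rises by fitted log2 fold change were those of ACTC1, KCNMB1 (at least 2950-fold higher), MYL7 (at least 573-fold), RPE65, CCDC190 (at least 309-fold), NPAS4 (at least 262-fold), VTCN1 (at least 186-fold) and CNN1 (log2 fold change 9.70). Fitted values are poorly determined for genes without a count in the control group. By their lower bounds CCDC190, NPAS4 and VTCN1 need not lie above CNN1 or ACTA2, and MYL7 need not lie above CNN1. KCNMB1 encodes the smooth muscle subunit of a potassium channel, MYL7 an atrial myosin light chain and CNN1 a smooth muscle calponin. RPE65, the retinoid isomerase gene of the retinal pigment epithelium, was at 101 ± 8.03 against 0.0286 ± 0.0248 CPM. The largest falls were those of MGP (-4.91), ALPP (-3.25), PAK6 (-3.25), C3 (-3.12), MOXD1 (-2.83), KCNJ2 (-2.81), DMRT2 (-2.71) and DCT (-2.66). C3 encodes complement component 3 and DCT a melanin-synthesis enzyme, and PAK6 shares exons with the readthrough gene BUB1B-PAK6.

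Of 36 measured MRTF-SRF cytoskeletal targets, 35 rose and 1 fell (median 2.18; camera, adjusted p = 1.74e-169, and adjusted p = 0.00349 with an estimated correlation). CNN1, with 2, 2 and 4 counts in the control vector libraries, was tested only because of its level with caMKL1. In the MKL1 comparison, which has the same controls, 34 members were measured. The count, median and p of this list are thus in part conditioned on the level with caMKL1. MYL9 (7.94), TAGLN (7.00), which overlaps PCSK7, TPM2 (3.44) and ACTB (1.46) rose, and TRIP6 (-0.55), outside the rule for named genes and named as the only exception, fell. Of 22 YAP-TAZ targets, 13 rose and 7 fell (median 0.20; camera, adjusted p = 0.00114, lost at adjusted p = 0.0812 with an estimated correlation), with rises of ANKRD1 (4.95), CCN2 (2.35) and CCN1 (2.14). Of 26 extracellular matrix genes, 13 rose and 8 fell (median 0.28; camera, adjusted p = 0.00907, lost at adjusted p = 0.398 with an estimated correlation), with rises of TNC (1.49), TIMP3 (1.36) and COL4A1 (1.21) and a fall of TGFBI (-1.99). LUM (1.91) and COL3A1 (1.61 ± 0.162 against 0.0465 ± 0.0475 CPM), used as fibroblast markers, rose alongside.

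**Figure D2:**
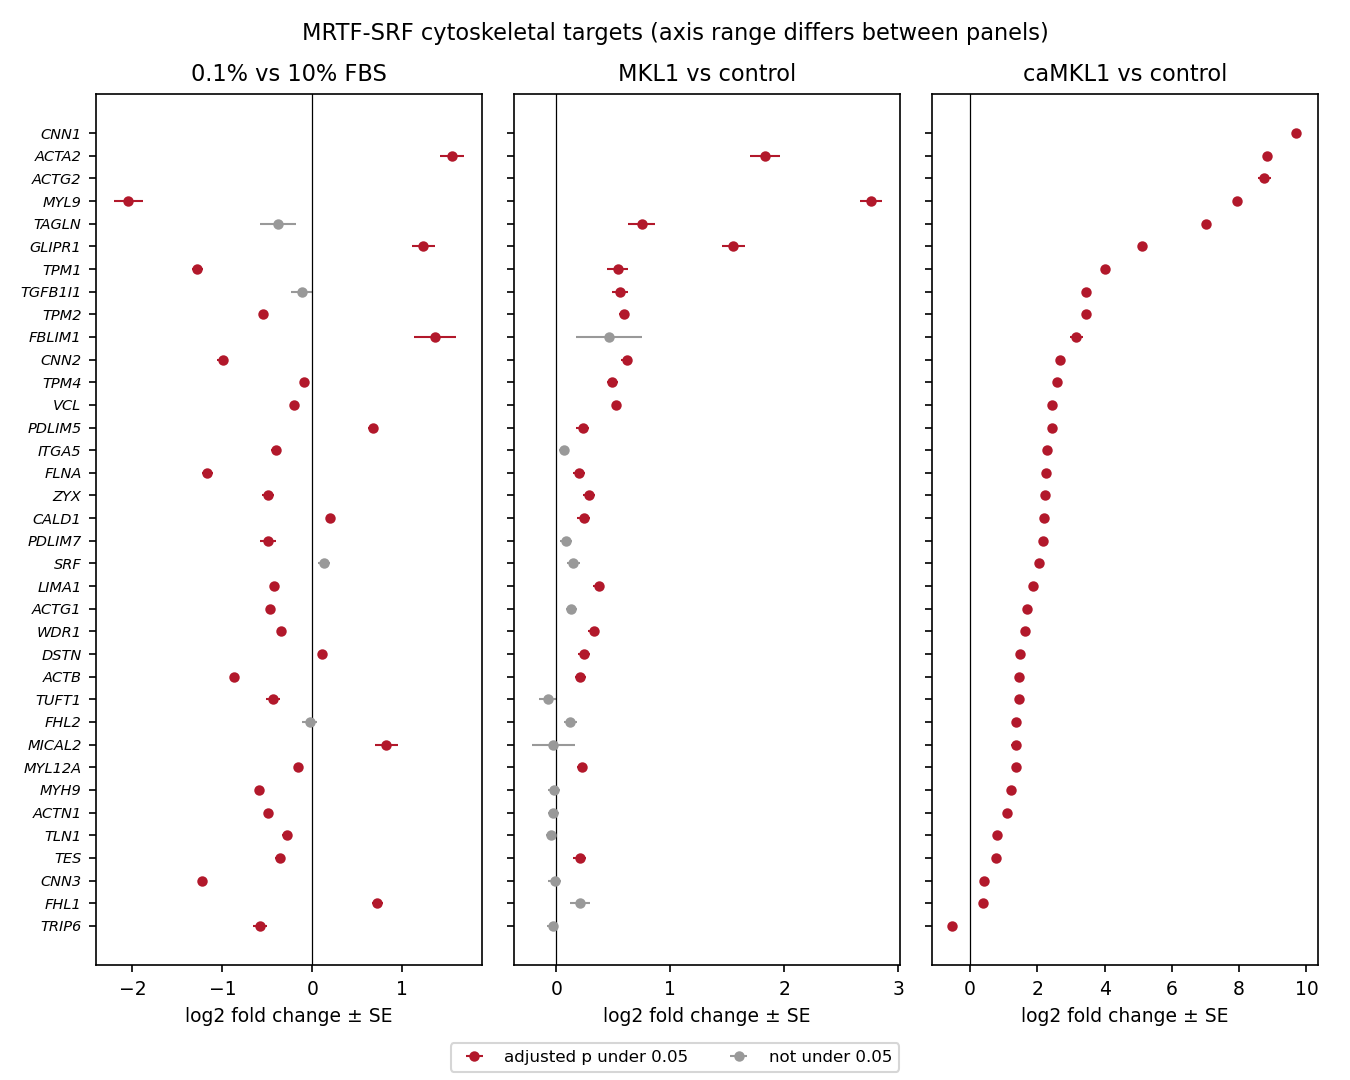
Log2 fold change (horizontal axis, with its SE as a bar) of each measured MRTF-SRF cytoskeletal target in 0.1% against 10% FBS, MKL1 against control vector and caMKL1 against control vector; red points have an adjusted p under 0.05, grey points do not, and the axis range differs between panels. The list medians are -0.37, 0.23 and 2.18, and genes without a point were too low to be tested.

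All 25 measured ribosome biogenesis genes fell (median -0.61; camera, adjusted p = 4.7e-11, and adjusted p = 0.0331 with an estimated correlation). NCL (-0.61), NOP56 (-0.65), RRP12 (-0.72) and PPAN (-0.72), the last sharing exons with PPAN-P2RY11, were among them. Of 37 genes of mitosis and DNA replication, 34 fell and 1 rose (median -0.43; camera, adjusted p = 5.18e-09, lost at adjusted p = 0.149 with an estimated correlation), among them MCM2 (-0.88), UHRF1 (-0.83), PCNA (-0.75) and TYMS (-0.98), which overlaps ENOSF1. Of 24 genes of the ATF4 stress response, 21 fell and 2 rose (median -0.40; camera, adjusted p = 0.00572, lost at adjusted p = 0.398 with an estimated correlation). TRIB3 (-0.70) and DDIT4 (-0.68) fell, and NUPR1 (2.13) and VLDLR (0.94) were the genes that rose.

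Of 12 measured checkpoint ligands, 10 rose and 0 fell (median 0.95; camera, adjusted p = 8.17e-07, lost at adjusted p = 0.0812 with an estimated correlation). CD274 was at 6.94 ± 0.666 against 2.15 ± 0.46 CPM (1.70 ± 0.167 SE, adjusted p = 6.8e-07, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment). CEACAM1 (ENSG00000079385, chromosome 19, 42507304 to 42561234), a ligand of the inhibitory receptor TIM-3, was at 20.4 ± 1.44 against 0.528 ± 0.0868 CPM (5.25 ± 0.146 SE). VTCN1 (ENSG00000134258, chromosome 1, 117143587 to 117210960), which encodes B7-H4, was at 8.23 ± 1.11 CPM with caMKL1 and had no count with the control vector. VTCN1 was tested only because of its level with caMKL1. It was not the only such ligand, as 10 were measured in the MKL1 comparison, which has the same controls. The count, median and p of this list are thus in part conditioned on the level with caMKL1. NT5E (1.07) and PVR (0.68) rose too. Of 27 interferon-stimulated genes, 12 rose and 7 fell (median 0.0593; camera, upward, adjusted p = 0.0015, lost at adjusted p = 0.164 with an estimated correlation). GBP1 (ENSG00000117228, chromosome 1, 89052319 to 89065360) was at 182 ± 8.67 against 6.54 ± 0.576 CPM (4.79 ± 0.0691 SE), and DDX58 (4.45), GBP2 (2.53) and ISG15 (2.36) rose, GBP2 sharing exonic bases with GBP7. Beside these immune genes TRAC, the T-cell receptor alpha constant gene, was at 3.85 ± 0.613 against 0.681 ± 0.0534 CPM (2.48 ± 0.228 SE), and fewer than 3 lymphocyte markers were high enough to test, so that list was not tested. CD4 also rose (1.22, adjusted p = 0.0223, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), at 0.697 ± 0.231 against 0.289 ± 0.144 CPM. The call of CD4 was lost without replicate 2 of caMKL1 (0.129), replicate 1 (0.0597) or replicate 2 (0.0842) of the control vector, and with DESeq2 (0.0704), within a range of 0.00771 to 0.129.

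The 20 genes of MHC class I antigen presentation (10 rose, 3 fell; camera, adjusted p = 0.24) and the 21 genes of lymphocyte adhesion, ligands and death receptors (5 rose, 8 fell; adjusted p = 0.774) did not pass as lists. NLRC5 (1.76) and TAP1 (1.28) rose and TAP2 (-0.51) fell in the former. In the latter, the NKG2D ligand gene ULBP2 (1.59) and FAS (0.53) rose, and ICAM1 (-0.46), TNFRSF1A (-0.34) and BID (-0.57) fell, with a median of -0.0289 and a mean of 0.0326. FAS shares 380 exonic bases with ACTA2 on the opposite strand. With caMKL1 ACTA2 had between 24587 and 33262 counts per library and FAS between 307 and 396, so the rise of FAS is uncertain. B2M (0.25) rose. No pass was found for the lists of immediate early genes (9 rose and 5 fell of 23; camera, adjusted p = 0.327), dedifferentiated melanoma (10 rose and 4 fell of 19; 0.211), cholesterol biosynthesis (4 rose and 13 fell of 22; 0.666), FOXO and quiescence genes (8 rose and 6 fell of 17; 0.774), MAPK pathway output (4 rose and 9 fell of 17; 0.666), glycolysis (8 rose and 7 fell of 21; 0.327) or lysosome and autophagy (10 rose and 4 fell of 22; 0.588). Within them ZFP36 (1.78), CAV1 (1.77), BIRC3 (3.62), CDKN1A (0.89) and DUSP5 (1.42) rose and KLF9 (-1.08) fell, and EGR1 was at 19.4 ± 1.26 against 19.4 ± 1.14 CPM (adjusted p = 0.981, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment) while FOS (0.51) rose. The melanocyte differentiation list (2 rose and 3 fell of 12; camera, adjusted p = 0.719), the fibroblast markers (2 rose and 0 fell of 5; 0.309) and the epithelial markers (2 rose and 2 fell of 4; 0.719) did not pass, though RAB27A (1.29), which overlaps PIGB, and KRT14 (1.79) rose and SOX10 (-0.24) fell. Adjusted over the list alone, 35 genes of mitosis and DNA replication, 9 matrix genes and 10 MAPK genes fell, and all other counts were as given. Of the 20 lists tested, 8 passed with the preset correlation and 2 with an estimated correlation. The matrix and interferon lists had 26 and 27 members measured here, and 25 and 26 with MKL1. Their calls may thus also be in part conditioned on the level with caMKL1.

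The direct comparison of caMKL1 with MKL1 asks how the active form differs from the wild-type form. MRTF-SRF targets and checkpoint ligands were higher with caMKL1. ACTA2 was at 1580 ± 54.7 CPM with caMKL1 against 12.1 ± 1.69 CPM with MKL1 (SD, n = 3 each; log2 fold change 7.02 ± 0.0698 SE). FN1 (ENSG00000115414, chromosome 2, 215360440 to 215436172) was at 820.2 ± 21.5 against 185 ± 3.6 CPM (2.15 ± 0.0475 SE), and SRF at 266 ± 5.02 against 71.3 ± 2.64 CPM (1.90 ± 0.0472 SE). In all, 7164 of 13720 tested genes passed, 3463 higher and 3701 lower with caMKL1, and 933 differed at least 2-fold (793 higher, 140 lower). Scaled by library totals alone, 2750 were higher and 4942 lower, so that 35.75% in place of 48.34% of the changed genes were higher.

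The largest rises by fitted log2 fold change were those of ACTC1, MYL7 (at least 588-fold higher), CCDC190 (at least 317-fold), NPAS4 (at least 269-fold), KCNMB1 (log2 fold change 10.47), VTCN1 (at least 191-fold), CNN1 (9.58) and PRND (at least 92.0-fold). By its lower bound PRND need not lie above ACTA2, and the other genes given a bound need not lie above CNN1. ACTC1 was at 317 ± 7.38 against 0.0137 ± 0.0238 CPM. The largest falls were those of UTP14C, DMBT1 (-3.61), SLX1B (-3.31), DCT (-3.16), MOXD1 (-2.71), F2RL1 (-2.50), PAK6 (-2.47) and MGP (-2.32). UTP14C had no count with caMKL1 and 4.56 ± 1.78 CPM with MKL1, at least 82.2-fold lower (adjusted p = 0.00348, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment), but it shares exons with ALG11. SLX1B has the near copy SLX1A, and its call (adjusted p = 0.0205 in edgeR with the same adjustment) was lost without replicate 1 of MKL1 (0.153), replicate 2 of caMKL1 (0.0802) or replicate 3 of caMKL1 (0.0603), within a range of 0.000745 to 0.153.

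Of 36 MRTF-SRF targets, 34 rose and 1 fell (median 1.94; camera, adjusted p = 2.95e-199, and adjusted p = 0.00014 with an estimated correlation). Of 12 checkpoint ligands, 10 rose and 0 fell (median 0.81, camera adjusted p = 3.1e-07, and adjusted p = 0.0164 with an estimated correlation), with CEACAM1 (3.67), CD274 (1.70), NT5E (0.81) and PVR (0.80) among them. VTCN1 here, and CNN1 among the MRTF-SRF targets, were tested only because of their level with caMKL1. VTCN1 was not the only such ligand, as 10 were measured in the MKL1 comparison. The counts, medians and p of both lists are thus in part conditioned on the level with caMKL1. Of 22 YAP-TAZ targets, 13 rose and 2 fell (median 0.24; camera, adjusted p = 7.44e-06, and adjusted p = 0.0489 with an estimated correlation), with rises of ANKRD1 (4.00), CCN2 (2.73) and CCN1 (2.28). Of 26 matrix genes, 17 rose and 6 fell (median 0.36; camera, adjusted p = 2.62e-10, lost at adjusted p = 0.0754 with an estimated correlation), TNC (1.69) and COL4A1 (1.33) among those that rose. All 25 ribosome biogenesis genes fell (median -0.39; camera, adjusted p = 5.46e-08, lost at adjusted p = 0.229 with an estimated correlation), BOP1 (-0.62) and POLR1B (-0.57) among them. Of 37 genes of mitosis and DNA replication, 27 fell and 1 rose (median -0.23; camera, adjusted p = 0.000645, lost at adjusted p = 0.619 with an estimated correlation), with a fall of TYMS (-0.63) and a rise of CHEK1 (0.71).

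Of 20 genes of MHC class I antigen presentation, 12 rose and 2 fell (median 0.15; camera, adjusted p = 0.0369, lost at adjusted p = 0.297 with an estimated correlation). NLRC5 (1.35) and TAP1 (1.08) rose. Scaled by library totals the MHC class I list did not pass (adjusted p = 0.0605; range over the camera alternatives 0.0291 to 0.297). Of 21 glycolysis genes, 13 rose and 2 fell (median 0.17; camera, adjusted p = 0.0126, lost at adjusted p = 0.619 with an estimated correlation), ENO2 (0.98) among them. Of 19 genes of the dedifferentiated state, 9 rose and 3 fell (median 0.12; camera, adjusted p = 0.0369, lost at adjusted p = 0.162 with an estimated correlation), with CAV1 (1.63) and ZEB1 (1.03) higher. The 27 interferon-stimulated genes (9 rose, 7 fell; median 0.0153, mean 0.363) did not pass (camera, upward, adjusted p = 0.055), with GBP1 at 3.02, DDX58 at 3.64 and ISG15 at 1.99. That list passed when scaled by library totals (0.0478), without replicate 1 (0.0487), 2 (0.0364) or 3 (0.0275) of MKL1, without replicate 2 of caMKL1 (0.0364), and without replicate 1 (0.0456), 2 (0.0377) or 3 (0.0419) of the control vector, within a range of 0.0275 to 0.244 over the camera alternatives. Its median was below 0 in 2 of these passes, at -0.0551 scaled by library totals and -0.00123 without replicate 2 of MKL1, so they do not show a rise of the list as a whole.

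The lists of immediate early genes (9 rose and 5 fell of 23; camera, adjusted p = 0.222), lymphocyte adhesion, ligands and death receptors (5 rose and 7 fell of 21; 0.922), cholesterol biosynthesis (5 rose and 7 fell of 22; 0.626), FOXO and quiescence genes (6 rose and 7 fell of 17; 0.405), melanocyte differentiation (2 rose and 4 fell of 12; 0.579), MAPK pathway output (5 rose and 9 fell of 17; 0.626) and lysosome and autophagy (7 rose and 4 fell of 22; 0.626) did not pass. Within them ULBP2 (1.70), ZFP36 (1.43) and DUSP5 (1.08) rose, and ICAM1 (-0.32) and MITF (-0.59) fell. The ATF4 list (5 rose and 13 fell of 24; camera, adjusted p = 0.177) passed without replicate 3 of MKL1 (0.0487; range over the camera alternatives 0.0487 to 0.735). Markers of lymphocytes (1 rose and 0 fell of 3), fibroblasts (2 rose and 0 fell of 6) and epithelia (2 rose and 2 fell of 6) each had a camera adjusted p of 0.626, with TRAC (2.68), LUM (0.87) and KRT14 (2.23) higher. Median, mean and test differed in sign for the lists of lymphocyte adhesion, ligands and death receptors, cholesterol biosynthesis and epithelial markers. Adjusted over the list alone, 35 MRTF-SRF targets rose and 14 ATF4 genes fell, and all other counts were as given. Of the 21 lists 9 passed with the preset correlation and 3 with an estimated correlation.

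**Figure D3:**
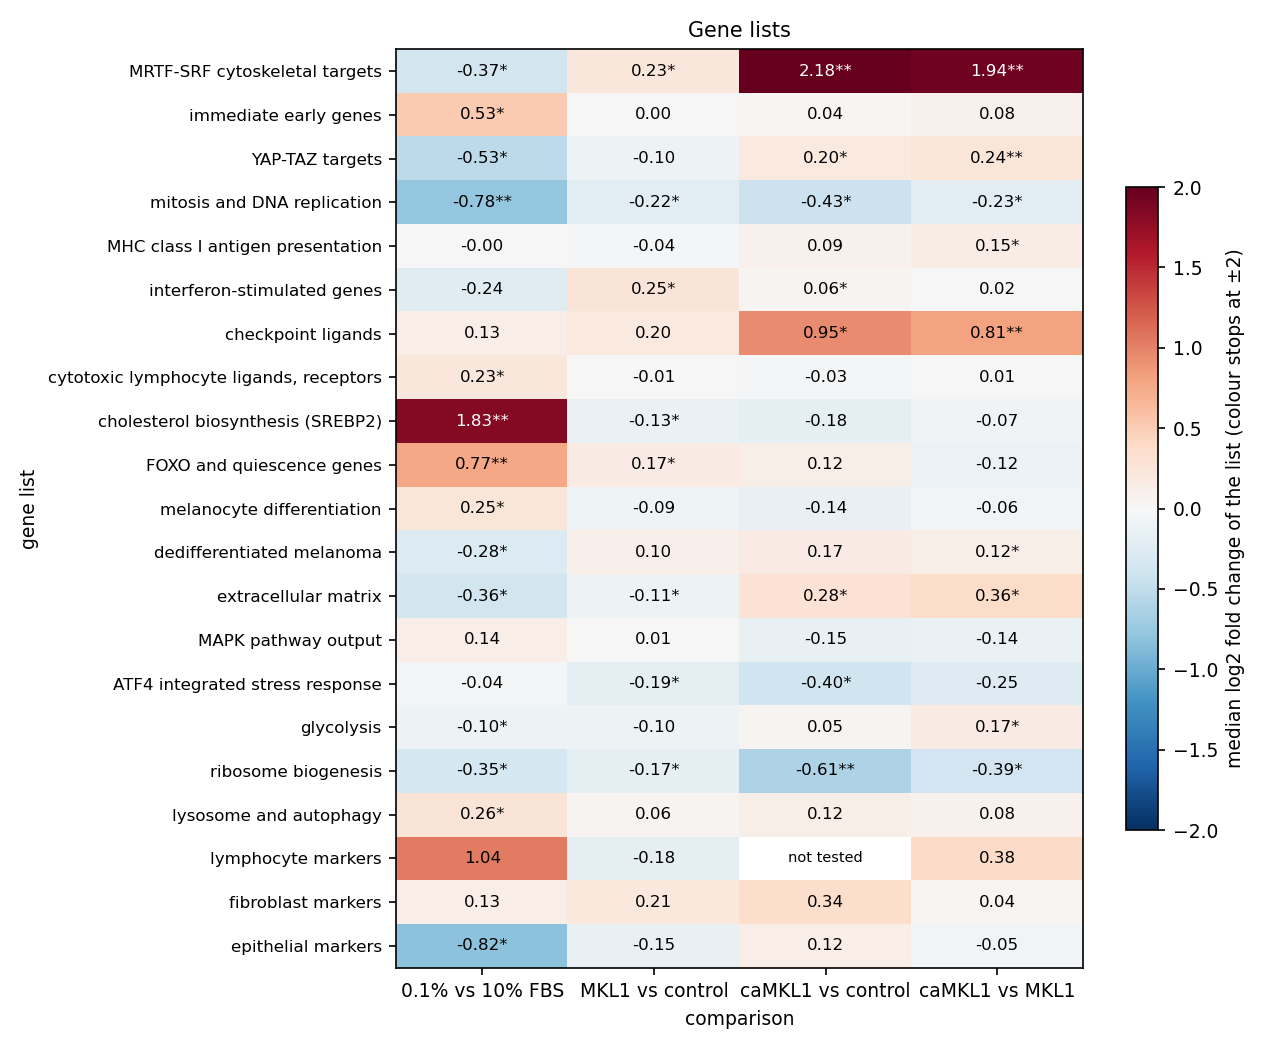
Median log2 fold change (colour and printed value) of each gene list (vertical axis) in the 4 comparisons (horizontal axis); 1 asterisk marks an adjusted p under 0.05 in camera with the preset correlation and 2 asterisks mark lists that also pass with an estimated correlation. Cholesterol biosynthesis has the highest median in the starvation comparison (1.83) and MRTF-SRF cytoskeletal targets have it with caMKL1 (2.18).

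Fold changes were also compared across genes between comparisons, with the caution that genes are not independent replicates. Starvation and MKL1, which share no libraries, had a Pearson r of 0.181 and a Spearman rho of 0.212 over 12986 genes, with 964 genes higher in both (642 for independent lists) and 1047 lower in both (655). Starvation and caMKL1 had an r of 0.151 and a rho of 0.226 over 13014 genes, with 1631 genes higher in both (1208 for independent lists) and 2092 lower in both (1417). MKL1 and caMKL1, which share their control libraries, had an r of 0.605 and a rho of 0.624 over 13293 genes, with 1478 genes higher in both (620 for independent lists) and 1679 lower in both (698). Unchanged groups simulated against those controls gave a mean r of 0.485 and a covariance of 0.0108, against an observed covariance of 0.123. The 3 control libraries cannot be split into parts of at least 2, so part of the excess may come from the shared controls.

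By the adjusted p-values the authors deposited, 5677 genes passed 0.05 in the starvation comparison, 3207 with MKL1 and 7494 with caMKL1. Of these, 5629, 3152 and 7369 also passed in edgeR, and 5615, 3143 and 7335 did so in the same direction. Of the authors' genes 5630, 3192 and 7384 were among those tested in edgeR. The genes that passed in both were 67.55%, 75.37% and 85.46% of those that passed in edgeR.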

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

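Each group holds 3 libraries, and list calls rest on the assumed correlation between genes. Of 5007 alternative values of 380 results for named genes that passed, 4956 still passed and 51 did not. Most named genes were picked in the main fit by size of change or smallest p, so this share says little of other changed genes. Of 456 alternative values of 39 lists that passed, 420 still did and 36 did not. In the order starvation, MKL1, caMKL1 and caMKL1 against MKL1, the counts of changed genes (8333, 4182, 8623 and 7164) were 7599, 3618, 7751 and 6399 with DESeq2, 8324, 4222, 8575 and 7080 with its size factors, 8287, 4217, 8701 and 7692 with library totals, 8482, 4213, 8862 and 7252 without a filter, 7729, 4112, 7839 and 6525 with a stricter filter, and 998, 177, 1282 and 933 at 2-fold or more. A joint fit of the 9 overexpression libraries gave 4828 (MKL1) and 8798 (caMKL1). With 1 library left out they ran from 7463 to 8412, 2595 (without MKL1 replicate 3) to 4094, 7829 to 8822 and 6194 to 7741. The lists that passed (14, 8, 8 and 9) were 3, 0, 2 and 3 with an estimated correlation, 19, 11, 17 and 19 with fry, 15, 8, 8 and 9 with library totals, and 13 to 15, 8 to 9, 8 to 8 and 9 to 11 with 1 library left out. The replicate number as a block gave 8668, 4569, 8710 and 7396 genes and 14, 8, 8 and 10 lists; same-number correlations were -0.199, 0.106 and 0.109 for starvation, 0.169, -0.0237 and 0.14 for MKL1, 0.147, 0.0469 and 0.00746 for caMKL1, and 0.157, 0.121 and 0.0185 between the forms, so not every sample correlated best with its own number. Fold-change correlations of starvation with MKL1 and with caMKL1 were 0.226 and 0.194 over genes of at least 10 CPM (0.181 and 0.151 over all), and 0.140 to 0.190 and 0.130 to 0.15 with 1 library left out (both lowest without control vector replicate 1); that of MKL1 with caMKL1 was 0.532 (without MKL1 replicate 3) to 0.626.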

Other observations

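The tests of 4 further gene lists were chosen only after the values had been seen, so their p-values are descriptive, and genes first named here fall outside the rule for named genes. The lists hold p53 targets, hypoxia-inducible genes, NF-kappaB targets and muscle contractile genes, adjusted over these 4 alone within a comparison. In 0.1% FBS 19 of 20 measured p53 targets rose and 0 fell (median log2 fold change 1.03; camera, adjusted p = 2.27e-23, and adjusted p = 0.00153 with an estimated correlation), with GDF15 (3.55), TP53INP1 (3.04), BBC3 (1.96) and MDM2 (1.61) among them. With MKL1 15 of 20 rose and 1 fell (median 0.309; camera, adjusted p = 4.11e-09, and adjusted p = 0.0105 with an estimated correlation), GDF15 (1.46) among them. With caMKL1 10 rose and 7 fell (camera, adjusted p = 0.466). Against MKL1, caMKL1 had 4 higher and 11 lower (camera, adjusted p = 0.045, lost at adjusted p = 0.0807 with an estimated correlation). Of 17 hypoxia-inducible genes 13 rose and 1 fell in 0.1% FBS (camera, adjusted p = 9.47e-10, and adjusted p = 0.00873 with an estimated correlation), with NDRG1 (1.18) and BNIP3 (1.06) higher and ANGPTL4 (-1.75) lower. With caMKL1 11 rose and 4 fell (camera, adjusted p = 0.000167, lost at adjusted p = 0.063 with an estimated correlation), and against MKL1 11 rose and 2 fell (camera, adjusted p = 7.49e-07, and adjusted p = 0.02 with an estimated correlation). With MKL1 7 rose and 4 fell (camera, adjusted p = 0.805), with a median of 0.195 although the test was downward.

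The tests of muscle contractile genes and NF-kappaB targets were likewise chosen only after the result was seen. Of the 20 muscle contractile genes 9 were measured in the caMKL1 comparison and 4 in the MKL1 comparison. ACTC1, MYL7, ACTA1, SYNPO2 and MYH11 had between 0 and 0.195 CPM with the control vector and were tested because of their level with caMKL1, so a count, median or p of the list with caMKL1 would be conditioned on the rise, and none is given. ACTC1 was at 313 CPM with caMKL1 and had no count with the control vector, and ACTA1 was at 15.2 against 0.0899 CPM. Of the 4 members measured in both comparisons, LMOD1 (5.53), TTN (2.68) and SMTN (0.906) rose with caMKL1, and TNNT1 (0.11, adjusted p = 0.423, edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment) did not pass. In the starvation comparison 1 of 4 rose and 3 fell (camera, adjusted p = 0.242), and with MKL1 2 of 4 rose (camera, adjusted p = 0.0515). Of 15 NF-kappaB targets 9 rose and 2 fell with caMKL1 (camera, adjusted p = 0.000499, and adjusted p = 0.0382 with an estimated correlation), with CXCL8 (3.42) and BIRC3 (3.62) higher and CCL2 (-3.87) lower. With MKL1 7 rose and 0 fell (camera, adjusted p = 0.00381, lost at adjusted p = 0.059 with an estimated correlation). Against MKL1, caMKL1 had 9 higher and 3 lower (camera, adjusted p = 0.00848, and adjusted p = 0.0358 with an estimated correlation), and starvation had 7 higher and 3 lower (camera, adjusted p = 0.188).

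The tests of the fall of ribosome biogenesis genes with caMKL1 were chosen only after the result was seen. Contractile transcripts take a larger share of the counts with caMKL1, so scaling could lower all other genes, but scaled by library totals the median log2 fold change of all 13558 tested genes was -0.0451 (SD 0.00407 over the 3 caMKL1 libraries) and that of the list -0.638 (SE 0.033). That SE comes from the spread between the 25 members, taken as independent, and not from the libraries. Expression level or transcript length could also lower a list, but of 10000 random lists matched on both in a permutation test, 0 had a median as low (p = 1e-04, the smallest this test can give; lowest random median -0.397). Both results speak against those explanations. A lower rate of growth with caMKL1 may explain the fall and was not tested.

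The tests of the rise of GBP1, GBP2, DDX58, ISG15 and checkpoint ligands with caMKL1 were chosen only after the result was seen. Lymphocytes in the cultures could carry such transcripts, and the 20 lymphocyte markers, TRAC included, summed to 5.89 CPM (SD 0.876, n = 3) with caMKL1 and 2.02 CPM (SD 0.367, n = 3) with the control vector, or 2.05 (SD 0.267) and 1.34 CPM (SD 0.415) for the 19 without TRAC. The sum of all 20 speaks against lymphocytes as the source of GBP1, GBP2, DDX58, NT5E, PVR, CEACAM1, NECTIN2 and VSIR, which rose by between 16.5 and 175 CPM, but leaves it open for ISG15 and the other risen checkpoint ligands, which rose by between 1.46 and 8.3 CPM, not clear of the sum by 2 SD of each. An interferon response could raise these genes too. Of the 27 measured interferon-stimulated genes 12 were higher, 7 were lower and 8 did not pass, with a median log2 fold change of 0.0593. These values argue against a rise shared by the whole list, although camera with the preset correlation was upward. The SD of 1.46 is the spread between the members, not the error of that median. A response confined to part of the list stays open. Regulation of single promoters by MKL1 and SRF, or by NF-kappaB, may also account for the rise and was not tested.

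The tests of the rise of ACTA2 in 0.1% FBS, against the fall of most MRTF-SRF targets, were chosen only after the result was seen. Reads of FAS could be counted for ACTA2, as they overlap on opposite strands, and their log2 fold changes differed by only -0.0356 (SE 0.153), as such reads would give. Against that, ACTA2 took 24.6% of the counts of both genes in 0.1% FBS while 8.93% of the exonic bases of FAS are shared, but how reads lie along FAS is not known from gene counts, so the explanation stays open. Reads shared with abundant actins could raise ACTA2, but the higher of the log2 fold changes of ACTB and ACTG1 was -0.476, which speaks against it. Strand-specific reads or a PCR across an ACTA2 intron would settle the matter.

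The tests on other splits of the libraries were chosen only after the result was seen. With 3 libraries against 3 there are 10 splits, too few for a share under 0.05, and each other split still carries part of the real difference. Each arm of such a split mixes both groups, so the real difference enters the spread within the arms. Few changed genes can then be called, so a count of 0 there is no support for the real split. In each of the 4 comparisons 1 of 10 splits, the real one, had as many changed genes; edgeR found 0 in every other split (at most 156, 394, 110 and 305 at an unadjusted p under 0.05, against 8806, 5736, 9074 and 7860 in the real ones), and no other tool was run on them. Of the gene lists, 14, 8, 8 and 9 passed in the real splits and at most 6, 5, 7 and 10 in another, so that 1, 1, 1 and 2 of the 10 splits had as many.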
